A study of Arabidopsis thaliana with 12 samples.

How the data were processed

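RNA was sequenced from whole rosettes of 4 Arabidopsis thaliana genotypes, with 3 libraries of each and 12 in all. Besides wild type (WT) there were mutants of VTC2 and of VTC4, here vtc2 and vtc4, and a line labelled as overexpressing VTC2 in the vtc2 background (OE). Per the labels' protocols, plants were 4 weeks old, had 8 h of light and 16 h of dark at 22 °C and 300 μmol photons m-2 s-1, and were frozen 30 min after lights on. Each library came from an independent pool of 8 rosettes. A strand-specific mRNA kit was used and read pairs of 75 bases were produced.

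The authors deposited one table of FPKM values (transcript abundance scaled for transcript length and library size) with 1 column per library. Per the submitters' processing notes, the tools were Trimmomatic 0.36, HISAT2 2.1.0, Cufflinks 2.2.1 and Cuffdiff, and the genome build was TAIR10. The annotation, the strand setting of the quantification and the normalization option were not given in the sources used here. The table held 33618 gene IDs, of which 32217 matched the later TAIR10.1 annotation, and 24296 were above 0 in at least 1 library. That annotation supplied symbols, chromosomes, gene overlaps, transcript lengths and base composition, and no expression values. Depth is unknown, since FPKM values keep no read totals. Low values moved in steps of 1 fragment, and the worth of 1 fragment relative to WT replicate 1 ranged from 0.914 to 1.01, so the libraries were of similar relative depth. The FPKM sums ranged from 684606 to 757484.

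Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), and fold changes are on that scale, which understates the change of weakly expressed genes. Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were kept, which left 17290. All 12 libraries entered 1 linear model with genotype as the only factor, so that all comparisons shared 1 estimate of spread per gene, and empirical Bayes moderation used a mean-variance trend. Tests were two-sided. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the genes of a comparison. The comparisons were vtc2, vtc4 and OE against WT, OE against vtc2, and vtc2 against vtc4.

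For gene groups, 28 lists with 511 genes were fixed before the data were examined, and 510 of the genes were in the table. The lists covered ascorbate biosynthesis, ascorbate regulators and side routes, the ascorbate-glutathione cycle, other antioxidant enzymes, auxin biosynthesis, tryptophan biosynthesis, auxin conjugation and catabolism, Aux/IAA genes, SAUR and early auxin genes, auxin transport and signalling, salicylate defence, jasmonate, abscisate with cold and drought, flavonoids, the circadian clock, photosynthesis, photoprotection, indole glucosinolates with camalexin, aliphatic glucosinolates, heat shock, rapid stress and touch, senescence with sugar starvation, iron, phosphate with inositol, cell wall expansion, root markers, floral markers and the guard cell lineage. Lists with at least 3 tested members, 26 in all, were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The second version left 0 of the 26 lists called in each of the 5 comparisons. Limma's fry was run as well; it asks whether the genes of a list move on balance one way and does not compare them with other genes.

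The rule for the genes named in the text was set together with the lists. VTC2 and VTC4 came first. Against WT, the 8 largest rises and 8 largest falls were named among called genes with a mean FPKM of at least 1 over both groups and no overlap between their replicate values. An overlap of this kind is absent by chance in 10% of genes with 3 libraries against 3. For the other comparisons, 4 and 4 were taken. Up to 4 called members of each list were added, by smallest adjusted p, and for ascorbate and auxin biosynthesis the 3 members with the smallest p where none was called.

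Comparisons that share WT libraries share their chance values. For that reason, 100 simulated data sets of unchanged groups gave the overlaps and covariances that arise without any effect. Each gene was simulated independently of the others, so joint movement of genes, as seen in the real libraries, was not reproduced. Unchanged groups yield almost no calls, so as many genes with the smallest p as were really called were also taken from each simulated set, a step added after seeing the data. In a planned set of 26 alternatives, 12 of which left out 1 library each, the pseudocount was set to 0.1 or 0.5, the filter was dropped or raised to a mean FPKM of 5, and values were rescaled by median ratios, to TPM or by quantiles. The remaining ones changed the model: only the groups compared, no trend, robust moderation, library weights, a 2-fold limit, a replicate block, or an estimated correlation in camera. Another 3 alternatives were chosen after seeing the data: removal of each library's trends with transcript length, GC content and purine content by splines with 4 degrees of freedom, removal of genes with transcripts under 300 bases, and the ascorbate list without VTC2 and VTC4.

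The method was tested on simulated data with the 17290 genes of vtc2 against WT. Changed genes were drawn only from those with a mean level of at least that of an FPKM of 5. Their folds were set on the log2(FPKM + 1) scale, so recovery of weaker genes was not measured. It called 59 of 67 genes changed 1.5-fold (88.1%), 66 of 67 changed 2-fold (98.5%) and 66 of 66 changed 4-fold (100%), with 12 calls among 17076 unchanged genes. A simulated list of 14 genes shifted by -0.5 was called with a camera adjusted p of 1.11e-22, and 0 other lists were called. The list was aliphatic glucosinolates, whose estimated correlation in the real data was 0.698. Simulated genes varied independently, so the check says nothing about calls of lists whose members move together. Figures and the annotation step used Python 3.11.15.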

Results

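The rosettes of 12 libraries were compared, 3 each from wild type, the ascorbate-deficient mutants vtc2 and vtc4, and the line labelled as VTC2 overexpression in vtc2 (OE). VTC2 encodes GDP-L-galactose phosphorylase and VTC4 encodes L-galactose 1-phosphate phosphatase, enzymes of the main plant route to ascorbate. The study's title ties ascorbate content to auxin biosynthesis, so the genes of both pathways were examined in every comparison. Between 16591 and 16962 genes per library reached an FPKM of 1. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, ran from 0.9788 to 0.989 within genotypes and from 0.9714 to 0.9899 between them. All group values below are means ± SD over n = 3 libraries, and fold changes are on the log2(FPKM + 1) scale.

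The transcripts of the disrupted genes matched the labels of the mutants. VTC2 (AT4G26850, chromosome 4) stood at 819 ± 77.4 FPKM in WT, 17.2 ± 2.79 in vtc2 and 783 ± 65.1 in vtc4. VTC4 (AT3G02870, chromosome 3) stood at 28.3 ± 2.67 FPKM in WT, 29.0 ± 1.48 in vtc2 and 0.373 ± 0.0837 in vtc4. In the libraries labelled OE, VTC2 reached 383 ± 24.6 FPKM, which was above vtc2 (log2 fold change 4.41, SE 0.11, limma adjusted p = 3.07e-10) and below WT (log2 fold change -1.09, SE 0.11, limma adjusted p = 0.00147). The construct was not given in the sources used here, so it is unknown whether transcripts of the transgene were fully counted in these FPKM values. Every direction below that uses these libraries is a direction of the libraries labelled OE.

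**Figure D1:**
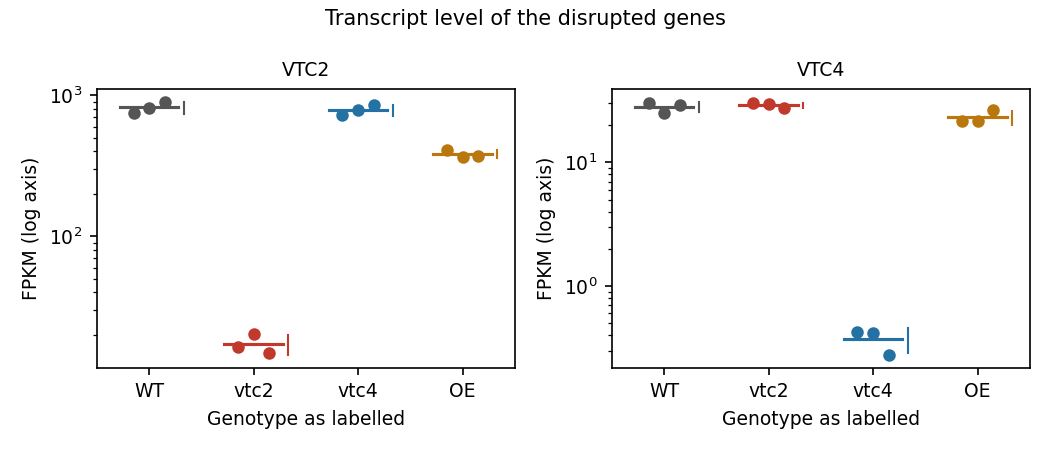
FPKM of VTC2 (left) and VTC4 (right) on a log axis for each of the 12 libraries, grouped by genotype as labelled; points are libraries, horizontal bars are means and vertical bars are the SD (n = 3). VTC2 averaged 17.2 in vtc2 and 383 in the libraries labelled OE against 819 in WT, and VTC4 averaged 0.373 in vtc4.

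Loss of VTC2 was examined by setting vtc2 against WT. Besides VTC2 (log2 fold change -5.50, SE 0.11, limma adjusted p = 2.42e-11), the squalene epoxidase-like gene SQP1 fell from 48.6 ± 7.7 to 19.9 ± 0.792 FPKM (log2 fold change -1.24, SE 0.1). MES18, a methyl esterase family member, fell from 16.5 ± 4.14 to 7.03 ± 0.125 (-1.10, SE 0.17). AT1G24580 (-1.14, SE 0.2) and AT1G74290 (-1.01, SE 0.15) fell as well. MRD1 was nearly absent in vtc2 at 0.213 ± 0.228 FPKM against 31.0 ± 0.921 in WT (log2 fold change -4.74, SE 0.12). AT5G11330 fell from 44.1 ± 1.17 to 18.8 ± 0.971 (-1.19, SE 0.069). Among rises, the defence gene PR5 went from 40.7 ± 9.97 to 133 ± 63.1 FPKM (log2 fold change 1.57, SE 0.33, limma adjusted p = 0.0289). Hsp70-2 went from 8.05 ± 1.05 to 23.9 ± 9.95 (1.39, SE 0.27) and the noncoding transcript AT3G15536 to 29.4 ± 13.1 in vtc2 (1.36, SE 0.31). The long noncoding AT3G05955 was listed at 0 in the 3 WT libraries and at 3.25, 2.19 and 2.33 FPKM in vtc2. AT1G75945 averaged 9.17 ± 1.6 FPKM in vtc2 against 0, 0.272 and 0 in the WT libraries. ENSRNA049757994 rose from 0.831 ± 0.574 to 3.68 ± 1.55. Some of the extreme values were uncertain. HEI10 (-1.31, SE 0.13) shares 1446 bases with MRD1 on the other strand. AT1G64795 (6.28, SE 0.22) and AT5G13565 (3.77, SE 0.75), with transcripts of 201 and 125 bases, lie wholly inside other genes on the opposite strand. With 1 library left out at a time, limma adjusted p reached its highest value without WT replicate 3 (0.119 for PR5, 0.152 for AT3G15536 and 0.0821 for Hsp70-2), without vtc2 replicate 2 (0.0523 for AT1G24580), without vtc2 replicate 3 (0.0927 for AT5G13565), and without WT replicate 1 (0.0675 for ENSRNA049757994).

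In total 523 of 17290 genes were called in vtc2 against WT, 138 higher and 385 lower. The median called gene differed by 1.53-fold among the higher and 1.3-fold among the lower ones. A difference of at least 2-fold held for 32 of them, 24 higher and 8 lower. The split by direction depended on scaling: after rescaling to TPM, 249 genes were higher and 183 lower (57.6% higher, against 26.4%). The number fell to 77 without vtc2 replicate 3, to 123 without vtc2 replicate 2 or without WT replicate 3, to 258 without WT replicate 1 and to 338 without vtc4 replicate 1.

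Ascorbate metabolism beyond VTC2 held called genes in several lists in vtc2, where 3.02% of all tested genes were called. Of 10 tested ascorbate biosynthesis genes, VTC2 alone was called (3 when adjusted over the list alone). The list was lower as a whole (median -0.13, limma camera adjusted p = 0.0199; adjusted p = 0.37 with an estimated correlation). Without VTC2 and VTC4, an alternative chosen after seeing the data, the list was not called (camera adjusted p = 0.268). Limma fry, which does not compare a list with other genes, gave an adjusted p of 2.54e-06 for ascorbate biosynthesis (0.0789 without VTC2 and VTC4) and 0.0459 for other antioxidants, all down. In the ascorbate-glutathione cycle, which recycles oxidized ascorbate, 3 of 22 genes fell and 0 rose (4 adjusted over the list alone). They were the chloroplast dehydroascorbate reductase DHAR3 (205 ± 12.5 to 164 ± 4.05 FPKM, log2 fold change -0.32, SE 0.058), the monodehydroascorbate reductase MDAR6 (-0.23, SE 0.054) and the ascorbate oxidase family gene AO3 (-0.26, SE 0.06). That list had a median of -0.10 (camera adjusted p = 0.0228, or 0.423 with an estimated correlation, and fry adjusted p = 0.0789, down). Its mean relative to WT was -0.149, 0.012 and 0.041 in vtc2 replicates 1, 2 and 3. In the WT libraries it was -0.008, -0.016 and 0.024, so vtc2 replicate 1 alone lay below them. Other antioxidant enzymes were lower (median -0.12, camera adjusted p = 0.0153; adjusted p = 0.423 with an estimated correlation), with 4 of 16 genes called and 8 when adjusted over the list alone. These were the superoxide dismutase FSD1 (886 ± 110 to 596 ± 21, -0.57, SE 0.1), the catalase CAT2 (AT4G35090, -0.37, SE 0.074), the peroxiredoxin PRXQ (-0.40, SE 0.068) and the glutathione peroxidase-like GPXL7 (-0.62, SE 0.14). MIOX1, a myo-inositol oxygenase of a proposed side route to ascorbate, fell from 3.64 ± 0.493 to 1.79 ± 0.26 (-0.73, SE 0.12), the 1 call among 10 regulators and side-route genes (1 adjusted over the list alone, camera adjusted p = 0.314). Without WT replicate 3, the camera adjusted p became 0.0626 for ascorbate biosynthesis, 0.0759 for the cycle and 0.0704 for other antioxidants. It became 0.293 for the cycle without vtc2 replicate 1. All 3 list calls ended with quantile normalization and with library weights, and the cycle's call also with TPM. For single genes the limma adjusted p reached its highest leave-one-out value without vtc2 replicate 3 (0.0753 for DHAR3, 0.129 for MDAR6, 0.169 for AO3, 0.0753 for FSD1, 0.109 for CAT2 and 0.0608 for PRXQ), without WT replicate 3 (0.135 for GPXL7), and without vtc2 replicate 2 (0.0516 for MIOX1). The calls of MDAR6 and AO3 each ended without any 1 of 10 libraries.

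Each auxin list held at most 2 called genes in vtc2. Among 11 tested auxin biosynthesis genes, the tryptophan aminotransferase gene TAR2 was the 1 called (2 adjusted over the list alone), from 5.34 ± 0.572 to 3.28 ± 0.532 FPKM (log2 fold change -0.57, SE 0.10, limma adjusted p = 0.016). The auxin biosynthesis list was not called (median -0.11, camera adjusted p = 0.292). The conjugating enzymes GH3.3 and GH3.5 rose, by 0.71 (SE 0.16) and 0.63 (SE 0.11) on the log2 scale. They were 2 of 11 conjugation and catabolism genes (4 adjusted over the list alone, camera adjusted p = 0.112; fry adjusted p = 0.0372, up). The auxin repressor gene IAA17 fell from 50.9 ± 3.87 to 35.1 ± 1.71 (-0.52, SE 0.068), the 1 call among 21 Aux/IAA genes (3 adjusted over the list alone). The Aux/IAA list had a median of -0.06 and a camera adjusted p of 0.0372 (0.423 with an estimated correlation, fry adjusted p = 0.109). Its median turned to 0.02 after rescaling to TPM. None of 16 tested SAUR and early auxin genes was called, over all genes or adjusted over the list alone (0 and 0, limma). Of these 16, 13 were negative, with a median of -0.23 (camera adjusted p = 0.00899, or 0.423 with an estimated correlation, and fry adjusted p = 0.136). By list mean relative to WT the libraries overlapped, as vtc2 replicate 1 (-0.08) lay above WT replicate 1 (-0.138). Several SAUR genes are near-identical tandem copies, so their single values are uncertain. Tryptophan biosynthesis (camera adjusted p = 0.955) and auxin transport and signalling (0.209) were not called, with 0 of 12 and 0 of 23 genes called. The limma adjusted p reached its highest leave-one-out value without vtc2 replicate 3 (0.071 for TAR2, 0.157 for GH3.3 and 0.0593 for GH3.5). Without WT replicate 3 the camera adjusted p became 0.131 for Aux/IAA and 0.0759 for SAUR genes. It became 0.116 for Aux/IAA without vtc2 replicate 2.

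Salicylate defence genes stood apart in vtc2 by size. All 27 tested genes had positive log2 fold changes, with a median of 0.73 (camera adjusted p = 3.27e-11; adjusted p = 0.423 with an estimated correlation; fry adjusted p = 0.135). Of these, 3 were called over all genes and 14 when adjusted over the list alone. The called ones were PR5, AED1 (27.1 ± 7.26 to 68.0 ± 25.8 FPKM, 1.25, SE 0.28) and the salicylate hydroxylase DMR6 (59.6 ± 11.8 to 120 ± 28.8, 0.98, SE 0.22). The list mean relative to WT was 0.24, 0.89 and 1.29 in the vtc2 libraries, and 0.02, 0.14 and -0.16 in WT. The calls of PR5, AED1 and DMR6 each ended without 4 or more single libraries, vtc2 replicates 2 and 3 and WT replicates 1 and 3 among them, with limma adjusted p of up to 0.119, 0.135 and 0.146.

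Lower lists in vtc2 included photosynthesis, where 19 of 21 genes were negative (median -0.16, camera adjusted p = 0.000374; adjusted p = 0.476 with an estimated correlation) and the median turned to 0.01 with quantile normalization. By limma 0 were called over all genes and 6 adjusted over the list alone, and near-identical copies in the LHCB and RBCS families make single members uncertain. Of 5 photoprotection genes, all negative (median -0.28, camera adjusted p = 0.00247; adjusted p = 0.37 with an estimated correlation; fry adjusted p = 0.0177), the quenching protein gene PSBS was called (1470 ± 157 to 1170 ± 66.1 FPKM, -0.33, SE 0.078), with 4 adjusted over the list alone. Jasmonate genes were lower (median -0.24, camera adjusted p = 0.00161; adjusted p = 0.471 with an estimated correlation), with the repressor JAZ6 (-0.39, SE 0.064) the 1 call of 28 and 6 adjusted over the list alone. For abscisate, cold and drought genes, 17 of 18 were negative and 0 were called either way (median -0.23, camera adjusted p = 0.00161; adjusted p = 0.423 with an estimated correlation). Aliphatic glucosinolate genes were negative in 15 of 15, with 0 called either way (median -0.16, camera adjusted p = 0.0211; adjusted p = 0.589 with an estimated correlation). Flavonoid genes had 0 of 17 called and 5 adjusted over the list alone (median -0.11, camera adjusted p = 0.0344; adjusted p = 0.423 with an estimated correlation). Phosphate and inositol genes had 2 of 9 called, IMPL1 (-0.33, SE 0.057) and the myo-inositol phosphate synthase gene MIPS1 (-0.42, SE 0.091), and 3 adjusted over the list alone. This list was lower (median -0.18, camera adjusted p = 0.0493, or 0.423 with an estimated correlation). Apart from photoprotection, the fry adjusted p of the lists in this paragraph ran from 0.135 for phosphate to 0.353 for aliphatic glucosinolates. By list mean relative to WT, the vtc2 and WT libraries did not overlap for photoprotection, flavonoids and aliphatic glucosinolates. For abscisate, WT replicate 1 (-0.222) lay below vtc2 replicates 2 and 3 (-0.193 and -0.167). For photosynthesis, WT replicate 2 (-0.142) lay below vtc2 replicates 1 and 2 (-0.107 and -0.118). For jasmonate, vtc2 replicate 3 (0.016) lay above WT replicate 1 (-0.104). For phosphate, WT replicate 1 (-0.166) lay below vtc2 replicates 2 and 3 (-0.056 and 0.063). Single libraries decided several of these lists. Without vtc2 replicate 1, the camera adjusted p became 0.239 for jasmonate, 0.0526 for abscisate, 0.166 for flavonoids, 0.0682 for aliphatic glucosinolates and 0.293 for phosphate. It became, without WT replicate 3, 0.159, 0.0759 and 0.131 for the last 3. Without WT replicate 2 aliphatic glucosinolates and phosphate both stood at 0.0881. The phosphate call held in 11 of 28 alternatives, and quantile normalization and library weights each ended the photosynthesis call. The limma adjusted p reached its highest leave-one-out value without vtc2 replicate 3 (0.171 for PSBS, 0.0593 for JAZ6 and 0.0608 for IMPL1), and without WT replicate 3 (0.123 for MIPS1).

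The remaining lists were not called in vtc2 against WT, although single members were. The clock gene CCA1 fell (409 ± 13.2 to 346 ± 11.7 FPKM, -0.24, SE 0.049; 1 of 18, 1 adjusted over the list alone, camera adjusted p = 0.314). The ferritin gene FER1 fell (-0.34, SE 0.068; 1 of 14, 2 adjusted over the list alone, 0.385), and the guard cell gene MYB60 fell (-0.41, SE 0.097; 1 of 10, 1 adjusted over the list alone, 0.123). None was called among 13 rapid stress and touch genes (1 adjusted over the list alone, camera adjusted p = 0.297), 13 senescence genes (1 adjusted over the list alone, 0.424), 16 indole glucosinolate genes (0 adjusted over the list alone, 0.953), 11 heat shock genes (0, 0.735) and 22 cell wall expansion genes (0, 0.903), all by limma. The indole glucosinolate and heat shock lists had positive medians and means with a camera direction of down. Tryptophan biosynthesis had a negative median and mean with a direction of up. Of the root markers 1 was tested, PYK10, which rose from 14.0 ± 3.19 to 27.8 ± 3.26 FPKM (0.95, SE 0.15). PYK10 stood at 25.6 ± 4.23 in vtc4 (0.83, SE 0.15, limma adjusted p = 0.139) and 20.1 ± 1.34 in OE (0.51, SE 0.15, 0.605), called in neither over all genes. Of the floral markers 2 were tested and 0 called (1 adjusted over the list alone). The limma adjusted p reached its highest leave-one-out value without vtc2 replicate 2 (0.11 for CCA1), and without vtc2 replicate 3 (0.0926 for FER1 and 0.158 for MYB60).

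**Figure D2:**
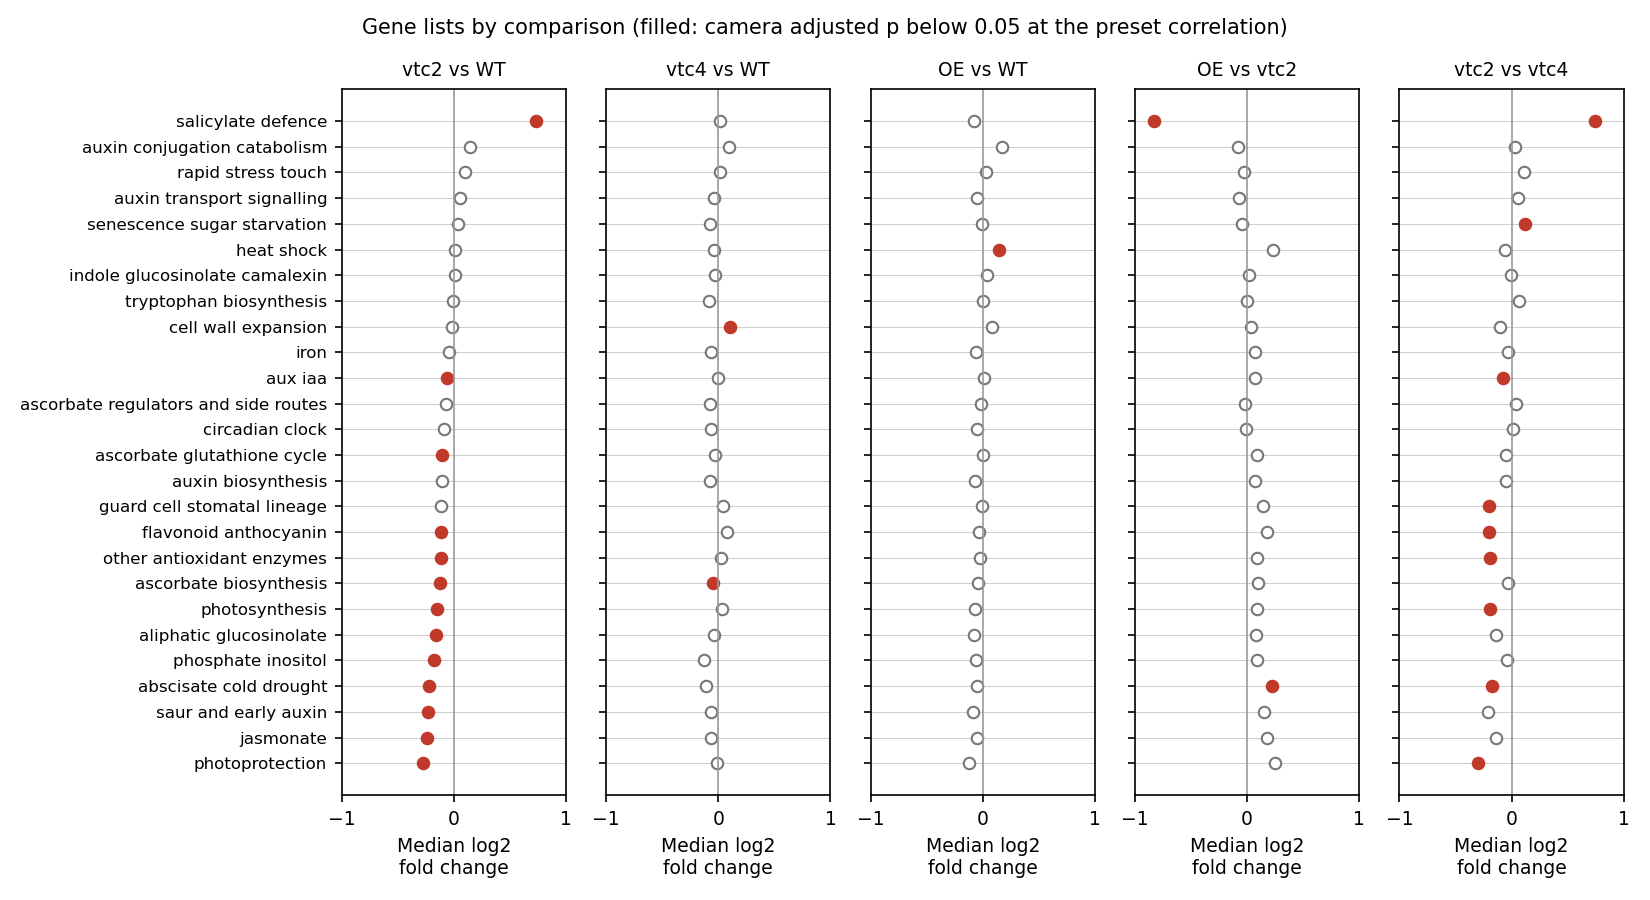
Median log2 fold change (x axis, log2(FPKM + 1) scale) of the tested members of 26 gene lists (y axis) in each of 5 comparisons; filled points had a limma camera adjusted p below 0.05 at the preset correlation, and 0 of the 26 lists did with an estimated correlation. Salicylate defence stood at 0.73 in vtc2 against WT and at -0.83 in OE against vtc2.

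Few genes were called when vtc4 was set against WT. In vtc4 against WT, 6 of 17290 genes were called, 2 higher and 4 lower. The 841 genes with an unadjusted limma p under 0.05 were no more than that threshold lets through among 17290 unchanged genes. VTC4 itself fell (log2 fold change -4.41, SE 0.096, limma adjusted p = 1.05e-10). MRD1 fell from 31.0 ± 0.921 to 0.286 ± 0.0921 FPKM (-4.64, SE 0.12) and AT5G11330 from 44.1 ± 1.17 to 18.9 ± 1.6 (-1.19, SE 0.069). HEI10, which overlaps MRD1, fell from 2.29 ± 0.0776 to 0.432 ± 0.0811 (-1.20, SE 0.13). AT1G75945 averaged 10.7 ± 0.85 and AT1G64795 stood at 95.4, 127 and 96.1 FPKM, with WT replicate 2 the 1 WT library above 0 for each, at 0.272 and 0.836. The HEI10 call ended with a pseudocount of 0.1, at a limma adjusted p of 0.0529. The number of called genes was 12 without WT replicate 3 and 10 without vtc2 replicate 2. That fewer genes were called in vtc4 than in vtc2 did not hold with only the groups compared, as given below.

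Among the listed genes, VTC4 alone was called in vtc4. In the ascorbate biosynthesis list it was the 1 call of 10 (1 adjusted over the list alone; median -0.05, camera adjusted p = 0.00587; adjusted p = 0.184 with an estimated correlation; fry adjusted p = 2.27e-05, down). The rest of the list without VTC2 and VTC4 was not called (camera adjusted p = 0.338, fry adjusted p = 0.689). VTC2 stood at -0.06 (SE 0.11, limma adjusted p = 1). None of 11 auxin biosynthesis genes was called (0 also adjusted over the list alone, camera adjusted p = 0.123). The 3 with the smallest p were TAA1 (6.81 ± 0.26 to 5.49 ± 0.18 FPKM, limma adjusted p = 0.968), NIT2 and NIT1 (log2 fold changes -0.27, -0.32 and -0.14), the last pair being similar tandem copies. Cell wall expansion genes were higher (18 of 22 positive, median 0.11, camera adjusted p = 0.0174; adjusted p = 0.751 with an estimated correlation), with 0 called by limma either way. Without vtc4 replicate 2, WT replicate 1 or WT replicate 2, the camera adjusted p of cell wall expansion became 0.502, 0.133 and 0.0809, and that of ascorbate biosynthesis became 0.0764 without WT replicate 3.

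Against WT, the libraries labelled OE differed in 3 genes, 1 higher and 2 lower, while 1044 had an unadjusted p under 0.05. VTC2 was lower, as given above. The calcium-dependent protein kinase gene CPK27 fell from 2.26 ± 0.256 FPKM in WT to 0.0752, 0 and 0.0239 in the libraries labelled OE (log2 fold change -1.65, SE 0.12, limma adjusted p = 5.54e-05). The vtc2 and vtc4 means stood at 2.47 ± 0.385 and 2.12 ± 0.3. AT1G75945 averaged 9.02 ± 1.11 FPKM (9.21-fold on FPKM + 1, limma adjusted p = 2.63e-07). None of 11 auxin biosynthesis genes was called (0 also adjusted over the list alone, camera adjusted p = 0.314), with TAR2 at -0.18, NIT2 at -0.33 and AMI1 at -0.15. Heat shock was the 1 list called, with 9 of 11 genes positive and 0 called either way (median 0.14, camera adjusted p = 0.0164; adjusted p = 0.682 with an estimated correlation). By fry 0 lists were called, the lowest adjusted p being 0.0809 for ascorbate biosynthesis. The camera adjusted p of heat shock became 0.219 without WT replicate 1, 0.0838 without WT replicate 3 and 0.086 without OE replicate 2. The number of called genes rose to 20 without vtc2 replicate 2, which enters the shared estimate of spread, and to 5 without WT replicate 3.

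**Figure D3:**
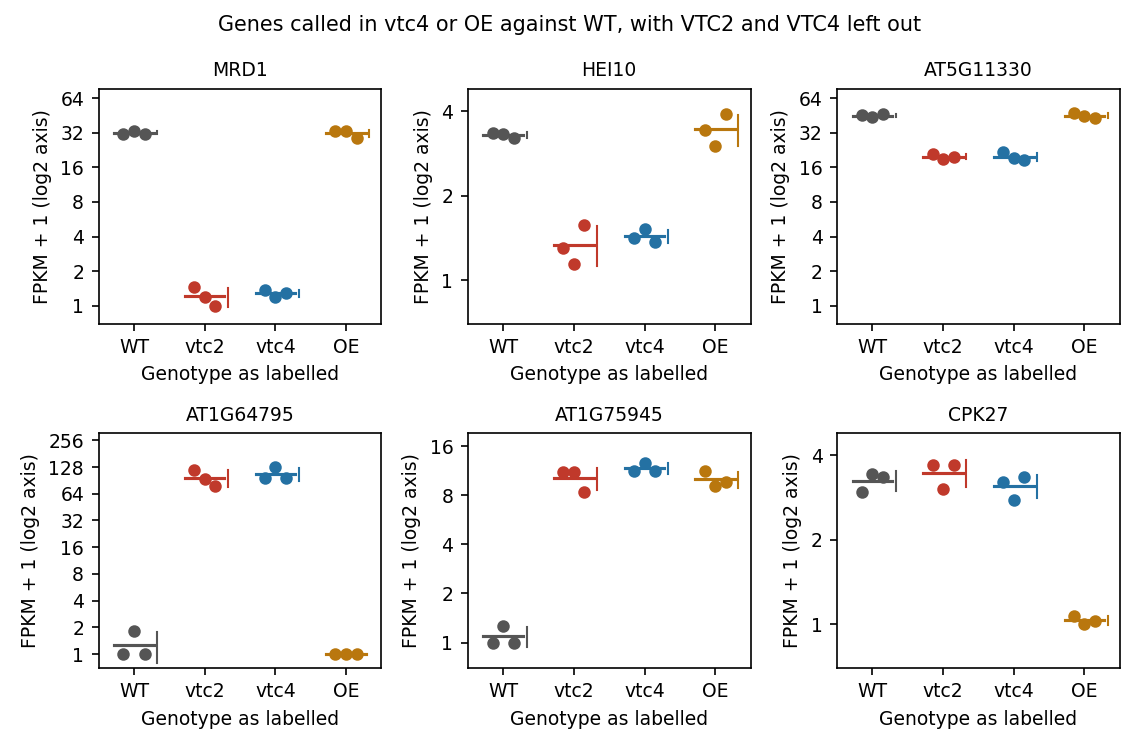
FPKM + 1 on a log2 axis for the 6 genes other than VTC2 and VTC4 called in vtc4 or in OE against WT, in each of the 12 libraries; points are libraries, horizontal bars are means and vertical bars are the SD (n = 3). MRD1, HEI10 and AT5G11330 were low and AT1G64795 high in vtc2 and vtc4, AT1G75945 was high in all but WT, and CPK27 was low in the libraries labelled OE.

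The libraries labelled OE were also set against vtc2, the background of that line. MRD1 was higher (30.7 ± 2.41 against 0.213 ± 0.228 FPKM, log2 fold change 4.72, SE 0.12). AT1G64795 was listed at 0 in all 3 libraries labelled OE against 118, 91.6 and 78.0 in vtc2. Within ascorbate metabolism, MIOX1 was higher (4.70 ± 0.222 against 1.79 ± 0.26, log2 fold change 1.03, SE 0.12), as were GLDH, the last enzyme of ascorbate synthesis (0.28, SE 0.07), DHAR3 (0.26, SE 0.058) and MDAR6 (0.27, SE 0.054). VTC5, the paralog of VTC2, was lower (19.3 ± 0.282 against 23.1 ± 1.01, -0.25, SE 0.061), as was the ascorbate oxidase family gene AO1 (AT4G39830, -0.74, SE 0.19). In all, 2 ascorbate biosynthesis genes rose and 1 fell of 10 (6 adjusted over the list alone). In the cycle 2 rose and 1 fell of 22 (4 adjusted over the list alone), with neither list called (camera adjusted p = 0.112 and 0.0743). By fry, ascorbate biosynthesis was the 1 list called (adjusted p = 3.74e-05, up), but VTC2 is a member and its rise defines the comparison. Without VTC2 and VTC4 it was not called (fry adjusted p = 0.141, camera adjusted p = 0.419). The limma adjusted p reached its highest leave-one-out value without OE replicate 3 (0.122 for GLDH), without OE replicate 1 (0.116 for DHAR3 and 0.0754 for MDAR6), without vtc2 replicate 2 (0.145 for VTC5), and without vtc2 replicate 3 (0.133 for AO1). The calls of GLDH, VTC5 and AO1 each ended without any 1 of 10 libraries.

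The tryptophan aminotransferase genes TAA1 and TAR2, of the first auxin step, rose in OE against vtc2, while TAR1 was too low to be tested. TAA1 rose by 0.47 (7.39 ± 1.43 against 5.00 ± 0.398 FPKM, SE 0.11, limma adjusted p = 0.0326) and TAR2 by 0.39 (4.61 ± 0.417 against 3.28 ± 0.532, SE 0.10, limma adjusted p = 0.0468), as 2 of 11 biosynthesis genes (3 adjusted over the list alone). That list was not called (camera adjusted p = 0.826; median 0.07, mean -0.00, direction up). IAA17 (0.60, SE 0.068) and IAA2 (0.44, SE 0.11) rose among 21 Aux/IAA genes (4 adjusted over the list alone, camera adjusted p = 0.0796). The limma adjusted p reached its highest leave-one-out value without OE replicate 1 (0.129 for TAA1 and 0.129 for IAA2), and without vtc2 replicate 2 (0.15 for TAR2). Other libraries ended these calls too. The TAR2 call ended without any 1 of 10 libraries, WT and vtc4 libraries that enter only the shared spread among them. For TAA1 there were 5 such libraries and for IAA2 4.

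All 27 salicylate defence genes were lower in the libraries labelled OE than in vtc2 by sign, 8 of them called and 17 adjusted over the list alone (median -0.83, camera adjusted p = 5.01e-11; adjusted p = 0.724 with an estimated correlation; fry adjusted p = 0.141). The libraries overlapped, however. The list mean relative to WT was -0.32, 0.62 and -0.55 in OE replicates 1, 2 and 3, and 0.24, 0.89 and 1.29 in vtc2, so OE replicate 2 lay above vtc2 replicate 1. The salicylate synthesis gene ICS1 fell (5.26 ± 1.86 FPKM against 13.3, 14.2 and 24.6 in the vtc2 libraries, -1.54, SE 0.21), as did PR5 (-1.82, SE 0.33), AED1 (-1.55, SE 0.28) and DMR6 (-1.25, SE 0.22). AIG1, a gene induced by an avirulence factor (-2.06, SE 0.49), and AT3G15536 (-1.84, SE 0.31) were lower too. In other lists, WRKY46 (-1.11, SE 0.28) was the 1 call of 13 rapid stress and touch genes (1 adjusted over the list alone, camera adjusted p = 0.478). SAG14 (-1.11, SE 0.26) was the 1 call of 13 senescence genes (1 adjusted over the list alone, 0.42). Higher genes included CAT2 (0.38, SE 0.074), FSD1 (0.49, SE 0.1), PRXQ (0.35, SE 0.068) and 2CPA (0.31, SE 0.081), 4 of 16 other antioxidant enzymes (9 adjusted over the list alone, camera adjusted p = 0.0743). So did VDE1 (0.32, SE 0.082), RBCS1B (0.33, SE 0.084), CCA1 (0.21, SE 0.049), IMPL1 (0.29, SE 0.057), JAZ6 (0.29, SE 0.064), CHS (0.38, SE 0.09) and HSP70B (0.36, SE 0.088), each the 1 called gene of its list (2, 3, 1, 2, 4, 1 and 2 adjusted over the list alone). Their lists, photoprotection, photosynthesis, clock, phosphate, jasmonate, flavonoid and heat shock, were not called (camera adjusted p = 0.0743, 0.0982, 0.873, 0.42, 0.0743, 0.0982 and 0.0743). Abscisate, cold and drought genes were positive in 17 of 18, with COR47 called (0.32, SE 0.066; 1 adjusted over the list alone; median 0.23, camera adjusted p = 0.0121; adjusted p = 0.724 with an estimated correlation). That list's adjusted p became 0.15 without vtc2 replicate 1 and 0.0777 with library trends of length, GC and purines removed, an alternative chosen after seeing the data. The limma adjusted p of single genes reached its highest leave-one-out value without OE replicate 1 (0.0663 for PR5, 0.0631 for AED1, 0.0615 for DMR6, 0.135 for AIG1, 0.157 for WRKY46, 0.0508 for AT3G15536, 0.087 for CAT2, 0.107 for FSD1, 0.0777 for PRXQ, 0.158 for VDE1, 0.16 for RBCS1B, 0.0853 for IMPL1, 0.118 for JAZ6, 0.137 for CHS and 0.129 for HSP70B), without vtc2 replicate 3 (0.115 for SAG14), and without vtc2 replicate 2 (0.144 for 2CPA, 0.142 for CCA1 and 0.0917 for COR47).

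In total 888 genes were called in OE against vtc2, 508 higher and 380 lower, 95 of them by at least 2-fold. After rescaling to TPM, 321 were higher and 537 lower (37.4% higher, against 57.2%). The number fell to 124 without OE replicate 1, 154 without vtc2 replicate 2, 183 without vtc2 replicate 3 and 329 without OE replicate 3. Long purine-rich transcripts were among the largest rises, such as AT5G40450 (21.7 ± 15 against 2.92 ± 1.61 FPKM, 2.41, SE 0.44) and the COP1-interacting protein gene CIP1 (28.7 ± 8.99 against 6.11 ± 2.79, 4.3-fold on FPKM + 1). Of the 172 tested genes richest in purines, a group chosen after seeing the data, 34 were called higher and 0 lower, and after removal of library trends, chosen after seeing the data, 13 were called higher and 14 lower. Without OE replicate 1 the limma adjusted p became 0.0596 for AT5G40450 and 0.0536 for CIP1.

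**Figure D4:**
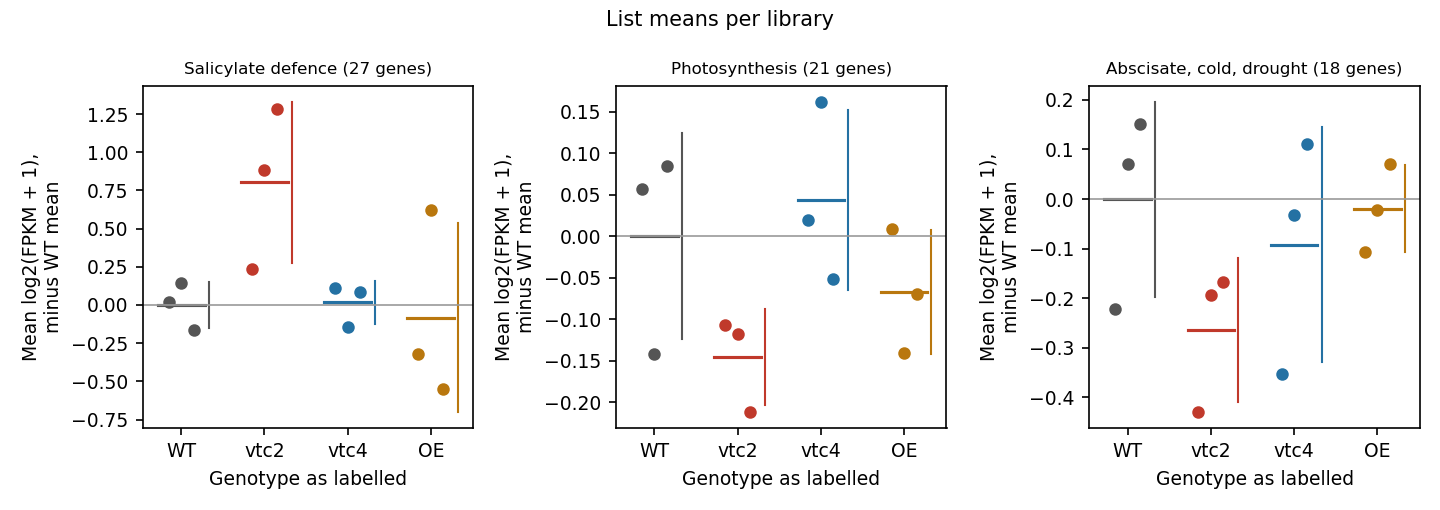
Mean log2(FPKM + 1) of the tested members of 3 gene lists in each library, minus the WT mean (y axis), by genotype as labelled (x axis); points are libraries, horizontal bars are means and vertical bars are the SD (n = 3). For salicylate defence the vtc2 libraries stood at 0.24, 0.89 and 1.29, and the libraries labelled OE at -0.32, 0.62 and -0.55; the scales of the 3 panels differ.

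The direct test of the 2 mutants, vtc2 against vtc4, called 236 genes, 80 higher and 156 lower in vtc2, and 36 of them by at least 2-fold. Salicylate defence was higher in vtc2 (27 of 27 positive, median 0.74, camera adjusted p = 1.3e-10; adjusted p = 0.64 with an estimated correlation). In it ICS1 (13.3, 14.2 and 24.6 FPKM against 7.78 ± 0.417, 1.01, SE 0.21) and PR5 (1.52, SE 0.33) were called, and 12 adjusted over the list alone. TAR2 was lower in vtc2 (3.28 ± 0.532 against 5.13 ± 0.14, log2 fold change -0.52, SE 0.1, limma adjusted p = 0.0348). It was the 1 call of 11 auxin biosynthesis genes (1 adjusted over the list alone, camera adjusted p = 0.984; median -0.05, mean 0.01, direction down). IAA17 (-0.45, SE 0.068), DHAR3 (-0.33, SE 0.058), PRXQ (-0.46, SE 0.068), CHS (-0.41, SE 0.09) and IMPL1 (-0.27, SE 0.057) were lower in vtc2. AT3G05955 stood at 2.59 ± 0.572 against 0.178 ± 0.0584 FPKM (1.60, SE 0.14) and AT1G56060 at 8.14 ± 6.07 against 1.58 ± 0.46 (1.64, SE 0.33). AT5G40450 (-2.24, SE 0.44), CIP1 (-2.04, SE 0.36) and the purine-rich AT2G22795 (-1.95, SE 0.33) were lower. After rescaling to TPM, 202 genes were higher and 117 lower (63.3% higher, against 33.9%). The number of called genes was 7, 8, 9, 14, 36 and 98 without vtc4 replicate 2, vtc2 replicate 3, vtc4 replicate 3, vtc2 replicate 2, vtc4 replicate 1 and OE replicate 1. It was 387 and 721 without WT replicate 3 and vtc2 replicate 1. VTC2, VTC4 and AT3G05955 stayed called whichever library was left out. For the others the limma adjusted p reached its highest leave-one-out value without vtc4 replicate 2 (0.0974 for IAA17, 0.122 for DHAR3, 0.0974 for PRXQ, 0.178 for CHS, 0.159 for IMPL1, 0.151 for AT5G40450, 0.122 for CIP1, 0.122 for AT2G22795, 0.126 for AT1G56060, 0.163 for ICS1 and 0.143 for TAR2), and without vtc2 replicate 2 (0.164 for PR5).

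Photosynthesis genes were negative in 21 of 21 in vtc2 against vtc4 (median -0.19, camera adjusted p = 6.68e-07; adjusted p = 0.64 with an estimated correlation), although the median was 0 with quantile normalization, which ended the call. By limma 0 were called, and 8 adjusted over the list alone. Other antioxidant enzymes (median -0.19, camera adjusted p = 0.00153; adjusted p = 0.444 with an estimated correlation) had PRXQ called of 16 and 11 adjusted over the list alone. Photoprotection (median -0.30, camera adjusted p = 0.00529; adjusted p = 0.444 with an estimated correlation) had 0 of 5 called and 3 adjusted over the list alone. Flavonoid genes were lower (median -0.20, camera adjusted p = 0.00416; adjusted p = 0.609 with an estimated correlation), with the chalcone synthase gene CHS the 1 call of 17 and 2 adjusted over the list alone. Guard cell genes were negative in 10 of 10 (median -0.20, camera adjusted p = 0.0188; adjusted p = 0.444 with an estimated correlation), with 0 called either way. Limma fry gave an adjusted p of 0.0375, down, for each of other antioxidants, photoprotection and guard cells. Aux/IAA genes (median -0.08, camera adjusted p = 0.036; adjusted p = 0.64 with an estimated correlation; 1 of 21 called, 5 adjusted over the list alone) and abscisate, cold and drought genes (median -0.18, camera adjusted p = 0.036; adjusted p = 0.81 with an estimated correlation; 0 called either way) were lower. Senescence and sugar starvation genes were higher (11 of 13 positive, median 0.12, camera adjusted p = 0.036; adjusted p = 0.64 with an estimated correlation; 0 called, 1 adjusted over the list alone). Without vtc4 replicate 3, the camera adjusted p became 0.0669 for flavonoids, 0.0621 for guard cells, 0.115 for senescence, 0.403 for abscisate and 0.0528 for Aux/IAA. The abscisate list stood at 0.445 without vtc2 replicate 1 and 0.0936 without vtc4 replicate 2. The Aux/IAA list stood at 0.0752 without vtc2 replicate 2 and 0.099 without vtc4 replicate 2, and senescence at 0.0697 without vtc2 replicate 2.

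The vtc2 and vtc4 profiles shared 5 called genes against WT, all in the same direction: MRD1, HEI10, AT5G11330, AT1G64795 and AT1G75945. Simulated unchanged groups sharing the same WT libraries gave 0 on average, and independent lists of these sizes would share 0.105. Those groups gave almost no calls, so a value of 0 says little. With as many top genes by p taken from each simulated set as were really called, 3.32 were shared on average and at most 6. With 6 genes called in vtc4, VTC4 itself among them, the real number could not exceed that simulated highest value, so the count alone decides nothing. Of the 523 genes called in vtc2, 432 had the same sign in vtc4, with a median of 0.08 in the direction of vtc2, and 345 in OE. For top genes of the simulated sets these were 471 (455 to 490) and 469 (452 to 485). Genes were simulated as independent, so these ranges may be too narrow. Across genes, the covariance of the log2 fold changes was 0.0215 against 0.0147 in the simulation, whose highest value was 0.0217. The correlation across genes was 0.449 against 0.491. Overlaps with OE against WT were 2 genes for vtc2 (VTC2 and AT1G75945; 0.01 simulated, 0.0525 for independent lists) and 1 gene for vtc4 (AT1G75945; 0 simulated, 0.000578 for independent lists). Simulated top genes shared 1.8 (at most 3) and 0.42 (at most 2). The covariances with OE against WT were 0.0143 for vtc2 (0.0148 simulated; correlation 0.313 against 0.493) and 0.0181 for vtc4 (0.0148 simulated; correlation 0.536 against 0.491). Since 3 WT libraries cannot be divided into separate control sets of at least 2, part of any excess may come from the shared controls. The 5, 2 and 1 shared genes became 11, 4 and 3 without WT replicate 3, and the last became 5 without vtc2 replicate 2.

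Most genes called in vtc2 differed the other way between the libraries labelled OE and vtc2. Of the 523 genes called in vtc2 against WT, 347 were called in the opposite direction in OE against vtc2, TAR2, IAA17, MIOX1, FSD1 and DMR6 among them, and 520 had the opposite sign. Simulated unchanged groups gave 0, which says little because they hold almost no calls. Independent lists gave 14.3, though both comparisons use the same vtc2 libraries. With equally many top genes by p, the simulated sets gave 148 (118 to 168) reversed and 468 (450 to 484) of opposite sign. These ranges may be too narrow as well, because simulated genes varied independently. In the real libraries, another split of vtc2 and OE gave 353 calls. Still called against WT in the same direction were 2, VTC2 and AT1G75945. The covariance across genes was -0.0503 against -0.0151 in the simulation, and the correlation was -0.758 against -0.499. The 347 became 55, 68, 87, 96, 178, 211 and 230 without vtc2 replicate 3, vtc2 replicate 2, OE replicate 1, WT replicate 3, WT replicate 1, OE replicate 3 and vtc4 replicate 1, and 548 without vtc2 replicate 1. The vtc4 libraries also lay opposite to vtc2. In vtc2 against vtc4, 516 of the 523 had the sign of vtc2 against WT. The median in the direction of vtc2 was 0.32 there and -0.35 in OE against vtc2. By sign, the reversal was thus not particular to the libraries labelled OE, and it does not by itself show an effect of the transgene.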

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

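Of the alternatives, 26 were planned and 3 were chosen after seeing the data. No called value of a named gene changed sign. In vtc2 against WT, 38 named genes were called and 8 stayed called in every alternative, and the same held for 5 of 6 in vtc4 against WT, 3 of 3 in OE against WT, 4 of 35 in OE against vtc2 and 3 of 15 in vtc2 against vtc4. Of 1040 alternative values for vtc2 against WT, 810 kept direction and side of the threshold and 229 lost the call. Other alternatives took some adjusted p values above the highest with 1 library left out, for example limma's for CCA1 and PSBS in vtc2 against WT, up to 0.395 and 0.281. The cause was not tested for any of the moved results below.

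Genes called in vtc2 against WT numbered 523, and 13 with only the groups compared, 331 without a trend, 821 with library weights and 32 at 2-fold. For vtc4 against WT they numbered 6, and 19 with only the groups compared and 10 with library weights. In OE against WT there were 3, and 7 with only the groups compared, and 5 with robust moderation and with library weights. OE against vtc2 had 888, and 93 with only the groups compared, 2913 with library weights and 95 at 2-fold. For vtc2 against vtc4 there were 236, and 13 with only the groups compared, 136 without a filter, 148 without a trend, 1196 with library weights and 36 at 2-fold. The genes reversed in OE against vtc2 numbered 347, and 227 without a trend, 673 with library weights and 26 at 2-fold. Shared calls of vtc2 and vtc4 numbered 9 with library weights, and those of vtc4 and OE 2 with robust moderation.

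With an estimated correlation, 0 lists were called in each of the 5 comparisons. Where 13, 2, 1, 2 and 9 lists were called, vtc2 against WT had 7 with quantile normalization and 6 with library weights. In vtc4 against WT there were 4 with only the groups compared, 5 with a mean FPKM of 5 and with median ratios, 6 with TPM, 7 with library weights and 1 with the ascorbate list without VTC2 and VTC4. OE against WT had 2 with pseudocounts of 0.1 and 0.5, with TPM and with the shortened ascorbate list, and 0 with a mean FPKM of 5 and with library trends removed. OE against vtc2 had 4 with a mean FPKM of 5, 7 with TPM and 1 with trends removed, and vtc2 against vtc4 had 5 with a mean FPKM of 5.

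Leaving out 1 library at a time gave 77 to 726 genes in vtc2 against WT, 6 to 12 in vtc4 against WT, 3 to 20 in OE against WT, 124 to 1302 in OE against vtc2 and 7 to 721 in vtc2 against vtc4. Lists ranged from 5 to 13, 1 to 9, 0 to 7, 1 to 7 and 5 to 12 in the same order. Shared calls ranged from 5 to 11 for vtc2 and vtc4, 2 to 4 for vtc2 and OE and 1 to 5 for vtc4 and OE, and the reversed genes from 55 to 548. The library named with a gene's highest adjusted p was often not the only one that ended its call. For PSBS in vtc2 against WT, 11 libraries did so.

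The replicate numbers did not pair the libraries: 6 of 18 same-numbered pairs deviated together with a correlation over 0.1, and 3 of 12 libraries correlated best with their own number. With the number as a replicate block, 602, 8, 3, 906 and 240 genes were called, 389 were reversed in OE, and 8 lists in vtc4 against WT and 5 in OE against vtc2 were called.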

Other observations

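All tests of explanations in this part were chosen after the results were seen. The numbers of called genes were also set against other splits of the same 6 libraries into 3 and 3; the 10 possible splits are too few for a share under 0.05, and the real split gave as many as any in 1 of 10 for every comparison. The real and the highest other counts were 523 and 1 in vtc2 against WT, 6 and 1 in vtc4 against WT, 3 and 1 in OE against WT, 888 and 353 in OE against vtc2, and 236 and 1 in vtc2 against vtc4. The split with 353 calls set vtc2 replicate 1 and OE replicates 1 and 3 against vtc2 replicates 2 and 3 and OE replicate 2, and 334 of its genes were higher in the latter, 15 salicylate defence genes among them. It shared 13 genes with the calls of the real split.

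The genes that were alike in vtc2 and vtc4 fell into separate classes. MRD1, HEI10, AT5G11330 and AT1G64795 differed from WT by -4.74, -1.31, -1.19 and 6.28 in vtc2 and by -4.64, -1.20, -1.19 and 6.44 in vtc4. A variant of the vtc2 stock handed on to the libraries labelled OE is argued against for these genes. Their OE against vtc2 differences were 4.72, 1.37, 1.19 and -6.58 (SE 0.12, 0.13, 0.069 and 0.22). The 4 were grouped by the lack of a call in OE against WT. That 4 of 4 were called the opposite way in OE against vtc2 largely follows from this choice. For AT1G75945 such a variant stays open for the OE line only, as its OE against vtc2 difference was -0.01 (SE 0.13). It would leave vtc4 unexplained, where the gene was as high (3.43 against WT, and -0.21, SE 0.13, in vtc2 against vtc4). A change that follows loss of VTC2 or VTC4 and is undone in the OE line is argued against by the gene's log2 fold change of 3.2 in OE against WT. AT1G75945 was thus high in all lines but WT. For the other 4, a change that follows loss of VTC2 or VTC4 and is undone in the OE line stays a candidate explanation. The level of VTC2 transcript alone would not give it, since vtc4 held VTC2 at 783 FPKM against 819 in WT. That 0 of 4 were called in OE against WT is no test of this candidate, because the 4 were set apart by that lack of a call. MRD1 and HEI10 also overlap, so they may not be separate results. A stock difference lost during the making of the OE line could give the same pattern and was not tested.

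Salicylate defence genes were higher in vtc2, but their level also varied within genotypes. The SD of the list mean was 0.62 among the libraries labelled OE and 0.53 in vtc2, against 0.15 in WT and 0.14 in vtc4, and the difference of means between vtc2 and WT was 0.80. A state of the harvested pool that varies within genotypes may therefore contribute, because the 0.62 among libraries labelled OE is close to that difference, and list members moved together around the genotype means (median correlation 0.84 across pairs of genes). Loss of VTC2 stays open as well: each vtc2 library lay above each WT library, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. The pool state and the genotype cannot be told apart for vtc2 with 3 libraries per group.

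Purine-rich transcripts, a group chosen after seeing the data, were called higher in OE than in vtc2 for 34 of the 172 richest (58.8% purines or more, against a median of 50.6%) and lower in vtc2 than in vtc4 for 14, while limma called 0 in vtc2, 0 in vtc4 and 0 in OE against WT (27, 49 and 49 at an unadjusted p under 0.05). The 172 deviated from their own means by -0.20 to -0.06 in the WT libraries, 0.09 to 0.19 in vtc4, 0.15 to 0.23 in the libraries labelled OE and -0.05, -0.53 and -0.05 in vtc2, so that vtc2 replicate 2 stood apart. The 34 had a median of -0.23 in vtc2 against WT (quartiles -0.35 and -0.16) and 0.94 in OE against vtc2 (lower quartile 0.60). They were chosen by the latter comparison, which raises the 0.94, so this pair of values decides nothing. Over all 172, each library labelled OE lay above each WT library. Loss of VTC2 and a return only to the WT level would not by itself give this. Measured VTC2 in the libraries labelled OE (383 FPKM) was below WT (819 FPKM), though transcripts of the transgene may not be fully counted. Each vtc4 library also lay above each WT library, with VTC2 at 783 FPKM in vtc4. The median over all 172 was 0.15 in vtc4 and 0.18 in OE against WT. For these genes, this argues against loss of VTC2 and its return as the only cause. A part in the difference between OE and vtc2 is not excluded. A library-wide trend with purines, GC and length cannot be told apart from other causes, since 13 of 34 and, in vtc2 against vtc4, 9 of 14 stayed called after the trends were removed, and a library batch could not be tested because the labels give none. For the largest, AT5G40450, CIP1 and AT2G22795, removal moved vtc2 against vtc4 from -2.24, -2.04 and -1.95 to -1.93, -1.78 and -1.29 (limma adjusted p = 0.0456, 0.0335 and 0.0246), so part of each difference went with the trend.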
